A study of Mus musculus with 80 samples.

How the data were processed

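Total RNA of whole hippocampus from 40 mice was measured on 80 Illumina mouse expression BeadChip arrays. Per the labels, each animal gave 1 array of the injected (IL) and 1 of the other (CL) hippocampus, tissue was kept in RNAlater, and RNA was labelled with biotin. The 12 groups are the combinations of hemisphere, treatment (KA or sham) and day (7, 28 or 60), with 8, 9 and 9 KA animals and 4, 5 and 5 sham animals. The summary of the design in the series text counts the sham groups of day 60 under KA; the labels of the single samples, used here, call them sham. Both arrays of an animal were linked by its animal number. Replicate numbers do not mark the animal: 6 of the 40 animals carry the same number on both arrays.

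The deposited table holds a background-subtracted bead intensity per probe that was not scaled between arrays, and beside each a deposited detection p-value against negative control beads. The deposited series matrix holds log2 values with the same distribution in all 80 arrays, so quantile normalized. Per the submitters' processing notes the tools were BeadStudio, GenomeStudio and Partek; their versions are not given in the sources used here. The intensity table has 25697 data lines in 2 parts. The first 21244 were used. The other 4453 were left out, because their columns are shifted against the header: of 3747 probe IDs found in both parts, the second part matched the first part of another array in 70 arrays, of the array itself in 2 and of none in 8 (99% of probes within 0.06 intensity units). In 1 array, CL sham day 60 replicate 4, the detection column was displaced by 1 line and was moved back, which changed the rank correlation with intensity from 0.208 to 0.988 (0.922 to 0.989 in the other arrays); 1 cell of it held text. In 80 of 80 arrays the series matrix ranked probes like the array's own intensity. The annotation gives 1 gene symbol for 19889 probes, several for 0 and none for 1355.

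Intensities were background corrected and quantile normalized with the neqc function of limma 3.58.1 (statmod 1.5.0, R 4.3.3; offset 16) and put on the log2 scale. A probe was kept when its detection p was under 0.05 on at least 4 arrays. This kept 16646 probes and removed 4598. The probe with the highest mean was taken for each symbol, which gave 11381 genes, 3035 of them with more than 1 kept probe. Among genes called on the IL side at day 7 that had another kept probe, 42 of 372 had another probe with the opposite sign. Depth on arrays is the signal over background: a mean of 61.3% of probes was detected per array, and the number of arrays limits the precision. A gene detected on too few arrays of a group was described as not well above background there, and its fold is given as at least the fold against the background level.

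Limma was fitted with 12 group means and animal as a random block (consensus correlation 0.0787). It tested 19 contrasts: KA against sham per side and day (6), the difference of that effect between the sides (3), IL against CL within KA and within sham (6) and the change of the KA effect between days (4). P values were adjusted by Benjamini and Hochberg over all genes per contrast, with a threshold of 0.05; all tests were two-sided. There were 35 gene lists, 17 of cell types and 18 of pathways, with 452 members, of which 360 had a probe and 334 were tested. Lists were tested with limma's cameraPR (preset correlation 0.01, adjusted over 35 lists and 6 contrasts, and separately over the 3 hemisphere differences), with an estimated correlation, with fry, and with slide as a block. The list score of an array is the mean deviation of its members from their means, tested with exact permutation of the animals, adjusted over the same 35 lists and 6 contrasts. Changes of members were also adjusted over the list alone. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) read the tables and drew the plots.

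The lists, contrasts, tests and the rule for naming genes were fixed before the data were examined. Named genes were the 8 strongest rises and falls per KA comparison, up to 4 called members per list, up to 5 per direction in the other contrasts, and a fixed set that includes Gfap, Aif1, Npy, Bdnf, Calb1, Adk, Kcnj10, Aqp4, Slc1a2, Gabrd, Fos, Dcx, Sst and Pvalb. Of these Calb1 and Kcnj10 had no kept probe. In arrays simulated with the group sizes, animals and gene means of the data and 1 spread per gene, 200 genes were changed 1.5-fold, 2-fold or 3-fold. Of these the fit recovered 47.8%, 76.1% and 100.0% at IL day 7, 35.8%, 80.6% and 90.9% at CL day 7, 52.2%, 88.1% and 100.0% at CL day 28 and 40.3%, 83.6% and 100.0% at CL day 60. It called 9, 5, 3 and 4 unchanged genes.

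Alternatives tried were no background correction, median scaling in place of quantiles, the series matrix values, no filter, a strict filter (detection p under 0.01 on at least 40 arrays), the mean of the kept probes, no animal block, animal as a fixed block, the replicate number as a block, slide as a block, slide 1 left out, a fit of only the groups compared, a trend with robust variance, array weights and each array left out in turn. Added after seeing the data were leaving out slides 4 and 9, the dimmest, and leaving out both arrays of 1 KA animal of day 7. Slides held unequal mixes of groups: KA and sham arrays of the same side and day shared 3, 2 and 4 slides on the IL side and 2, 2 and 2 on the CL side. Residuals of arrays on the same slide had a median correlation of 0.140 (236 pairs), those of both sides of an animal 0.080 (40 pairs), and those with the same replicate number on both sides of a group 0.043 (34 pairs).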

Results

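The data are 80 Illumina mouse expression BeadChip arrays, which measure messenger RNA levels with bead-bound probes. They were made from hippocampal RNA of 40 male C57BL/6J mice, operated on at 12 weeks of age. Each animal received 50 nl of either 20 mM kainic acid (KA), an agonist of kainate-type glutamate receptors used to model mesial temporal lobe epilepsy, or saline (sham) in the right dorsal hippocampus. The hippocampus on the injected (ipsilateral, IL) side and the one on the other (contralateral, CL) side of each animal were arrayed separately. Tissue was taken 7, 28 or 60 days after surgery. KA animals numbered 8, 9 and 9 at these days, and sham animals 4, 5 and 5. The arrays lay on 11 slides of up to 8 positions. Between 46.8% and 66.9% of probes were detected per array (mean 61.3%, SD 3.8), and the median deposited intensity per array lay between 17.3 and 70.0. Slides 4 and 9 were the dimmest, with 56.8% and 51.4% of probes detected on average. The first principal component carried 16.4% of the variance and followed the 12 groups of hemisphere, treatment and day (R² = 0.80). The second carried 9.8% and followed the slide (R² = 0.89). Differences below are log2 differences of limma with their SE, and the number of arrays limits their precision.

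**Figure D1:**
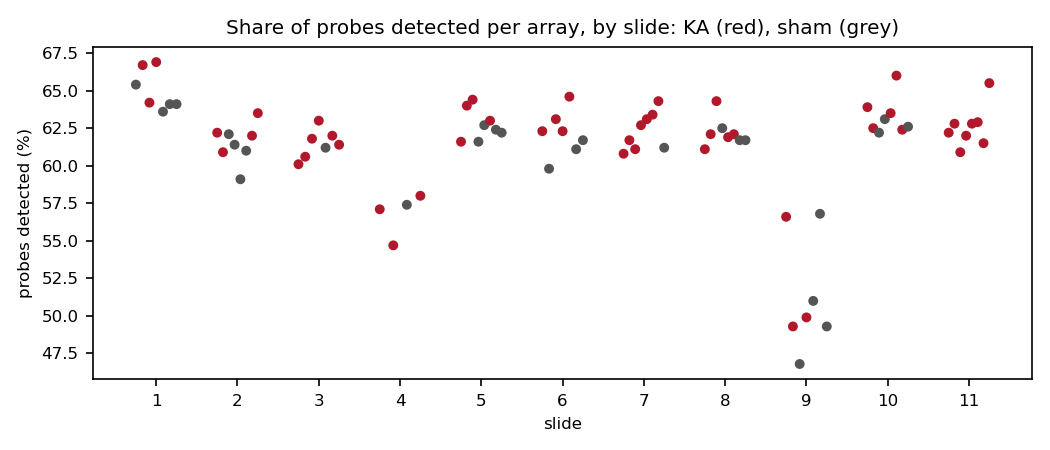
Percent of probes detected (vertical axis) on each of the 80 arrays, grouped by slide (horizontal axis), with KA arrays in red and sham arrays in grey. Arrays on slides 4 and 9 lie lowest, down to 46.8%.

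The comparison of KA and sham animals on the injected side asked how the hippocampus that received kainate differed from one that received saline. At day 7, genes of microglia, reactive astrocytes, complement, chemokines and interferon signalling were higher in KA. Of the activated microglia and macrophage markers, 12 of 13 rose and 0 fell (12 and 0 adjusted over the list alone). Gpnmb, a glycoprotein of phagocytic macrophages, rose by 3.75 ± 0.45 and Cd52, a leukocyte surface antigen, by 3.59 ± 0.43. Of the reactive astrocyte genes, 12 of 17 rose and 0 fell (15 and 0 adjusted over the list alone). Lcn2, which encodes the secreted protein lipocalin 2, was at least 24.4-fold higher (adjusted p = 1.22e-07), because it was not well above background in sham. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.77 ± 0.51, and Gfap, the intermediate filament protein of astrocytes, by 2.45 ± 0.38 (adjusted p = 7.04e-07, 7 of 8 KA arrays above every sham array). Of the complement genes, 6 of 6 rose and 0 fell (6 and 0 adjusted over the list alone), led by C1qa at 2.64 ± 0.31. Of the cytokines and chemokines, 14 of 15 rose and 0 fell (14 and 0 adjusted over the list alone), with Cxcl10, a chemokine induced by interferon, at 4.00 ± 0.50. Of the interferon response genes, 10 of 10 rose and 0 fell (10 and 0 adjusted over the list alone), with Usp18 at 3.10 ± 0.42.

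Genes of lysosomes, antigen presentation, dividing cells and the extracellular matrix were also higher on the injected side at day 7. Of the lysosome genes, 11 of 12 rose and 0 fell (11 and 0 adjusted over the list alone), among them Gusb, the enzyme beta-glucuronidase (2.20 ± 0.27). Of the antigen presentation genes, 10 of 11 rose and 0 fell (11 and 0 adjusted over the list alone), with the costimulatory protein gene Cd86 at 1.94 ± 0.28. Of the homeostatic microglia markers, 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone). Of the cell cycle genes, 6 of 11 rose and 0 fell (9 and 0 adjusted over the list alone). These included Birc5, the mitotic protein survivin (1.20 ± 0.22), and Cdk1, the mitotic kinase, which was not well above background in sham and at least 2.08-fold higher. Of the extracellular matrix genes, 7 of 12 rose and 0 fell (9 and 0 adjusted over the list alone), with the matrix glycoprotein tenascin C, Tnc, at 1.46 ± 0.30. Of the astrocyte identity genes, 4 of 13 rose and 0 fell (6 and 0 adjusted over the list alone), with Aqp4, the water channel of astrocyte endfeet, at 1.41 ± 0.31.

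Neuronal genes moved in both directions at day 7 on the injected side. Of the neuropeptides and trophic factors, 6 of 15 rose and 2 fell (8 and 2 adjusted over the list alone). Pdyn, the precursor of dynorphin, rose by 1.55 ± 0.37. The 2 that fell, named after their values were seen, were Tac1, the precursor of substance P (-0.84 ± 0.25, adjusted p = 0.0922 without sham replicate 1), and Chgb, a secretory granule protein (-0.46 ± 0.13, adjusted p = 0.0563 without sham replicate 4). Outside the lists, the neuropeptide genes Cartpt and Trh, the precursor of thyrotropin-releasing hormone, rose by 4.18 ± 0.72 and 3.90 ± 0.61. Of the immediate early genes, which neurons transcribe after activity, 3 of 13 rose and 0 fell (6 and 0 adjusted over the list alone), with Fos at 2.29 ± 0.53. Of the interneuron markers, 0 of 9 rose and 3 fell (0 and 3 adjusted over the list alone). Cort, the precursor of cortistatin, fell by 1.11 ± 0.23 (adjusted p = 0.000323) and Htr3a, the ionotropic serotonin receptor subunit, by 1.04 ± 0.24 (adjusted p = 0.000885). The calcium-binding protein gene Pvalb (-0.48 ± 0.33, adjusted p = 0.461) and the peptide gene Sst (-0.57 ± 0.40, adjusted p = 0.477), 2 common interneuron markers, did not pass. Dlg4, the postsynaptic scaffold PSD-95, and Scn3b, a sodium channel subunit, fell by 0.87 ± 0.20 and 0.94 ± 0.22. Dlg4 was the 1 of 13 synapse genes that fell (0 and 1 adjusted over the list alone).

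In total 850 genes were higher and 345 lower in KA on the injected side at day 7 of 11381 tested (limma, adjusted p under 0.05), and 397 of them differed more than 2-fold. Under median scaling, which moved the median of all genes to -0.104, the split was 637 and 142. Of the 35 lists, 13 were higher and 1, the interneurons, lower by limma's cameraPR, and 11 and 1 with an estimated correlation. The mean shift of the activated microglia list was 2.37 (adjusted p = 1.65e-29), 2.40 with slide as a block and 1.23 to 2.86 within the 3 slides that held both groups. Reactive astrocytes shifted by 1.88 (adjusted p = 4.21e-24; 1.92 with slide as a block and 0.90 to 2.29 within slides). Interneurons shifted by -0.52 (adjusted p = 0.00902; -0.58 with slide as a block and -0.77 to -0.46 within slides), and the pan-neuronal markers, none of which passed, by -0.27 (adjusted p = 0.251). Cell cycle genes shifted by 0.78 (adjusted p = 2.5e-10). Neuropeptides and trophic factors (adjusted p = 0.0273) and immediate early genes (adjusted p = 0.0454) were lost with an estimated correlation (adjusted p = 0.27 and 0.517). With slide as a block both were lost as well (adjusted p = 0.0891 and 0.131). The immediate early list was also lost without IL KA replicate 2, 3, 7 or 8 or IL sham replicate 1, 2 or 4 (adjusted p from 0.0516 to 0.113). All 14 called lists kept their direction with slide as a block and within each of the 3 slides. KA replicate 8 lay near the sham arrays in the glial and immune lists, with an activated microglia score of -0.28 against 1.84 to 2.38 in the other KA arrays; without it 1493 genes passed.

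Lists of principal neurons and of ion channels did not pass by cameraPR on the injected side at day 7. The CA1 pyramidal cell list shifted by -0.48 (adjusted p = 0.0622), the CA2 and CA3 list by -0.42 (adjusted p = 0.143) and the dentate granule cell list by 0.30 (adjusted p = 0.45). Synapse genes shifted by -0.27 (adjusted p = 0.0856) and sodium, calcium and HCN channels by -0.26 (adjusted p = 0.144). GABA receptors, which carry fast and slow inhibition, shifted by -0.34 (adjusted p = 0.143). Glutamate receptors shifted by -0.23 (adjusted p = 0.148). By the exact permutation test of the list score per array, both receptor lists were lower, with adjusted p = 0.0393 and 0.0296 and 7 of 8 KA arrays below every sham array in each. Limma's fry, which does not compare a list with other genes, called both lower (adjusted p = 0.00515 and 0.0148), and also CA1 (0.00441), sodium, calcium and HCN channels (0.0145), potassium channels (0.0292) and synapse genes (0.0375).

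**Figure D2:**
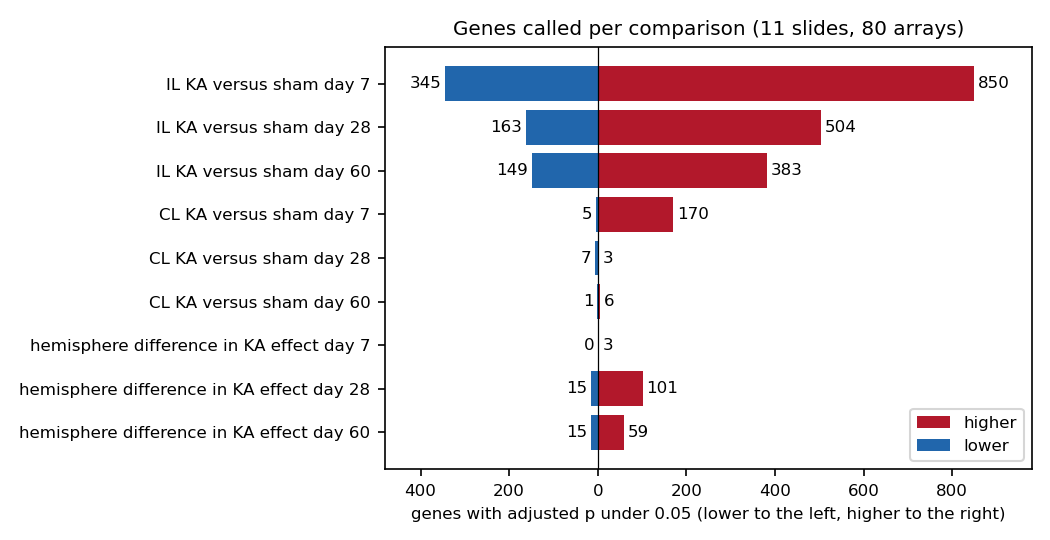
Number of genes higher and lower (adjusted p under 0.05, limma) in each comparison. The injected side had 850, 504 and 383 genes higher in KA at days 7, 28 and 60, and the other side 170, 3 and 6.

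At day 28, microglial, astrocytic and complement genes were higher in KA on the injected side, and so was a group of neuropeptide genes. Of the activated microglia and macrophage markers, 9 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), led by Cst7, a cystatin of activated microglia (3.56 ± 0.41), and Gpnmb (3.36 ± 0.41). Of the reactive astrocyte genes, 10 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), with Lcn2 at least 11.5-fold higher (adjusted p = 3.96e-06) and Gfap at 2.45 ± 0.34. Of the complement genes, 5 of 6 rose and 0 fell (5 and 0 adjusted over the list alone), with C4b at 2.29 ± 0.30. Of the neuropeptides and trophic factors, 10 of 15 rose and 0 fell (11 and 1 adjusted over the list alone). Pdyn rose by 2.30 ± 0.34, Scg2, the precursor of secretoneurin, by 1.84 ± 0.40, Bdnf, a neurotrophin, by 1.59 ± 0.30 and Npy, neuropeptide Y, by 1.14 ± 0.24 (adjusted p = 0.000839, 9 of 9 KA arrays above every sham array). Cartpt and Trh rose by 5.39 ± 0.65 and 4.36 ± 0.56. Ccn5, a matricellular protein, was at least 5.15-fold higher and had the lowest adjusted p of the comparison (7.31e-14). Cort fell by 1.15 ± 0.21.

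Other immune lists had members that passed at day 28 on the injected side. Of the cytokines and chemokines, 6 of 15 rose and 0 fell (9 and 0 adjusted over the list alone), with Ccl4 at 2.76 ± 0.42. Of the interferon response genes, 6 of 10 rose and 0 fell (8 and 0 adjusted over the list alone), with Ifit3 at 1.65 ± 0.31. Of the lysosome genes, 5 of 12 rose and 0 fell (7 and 0 adjusted over the list alone), and of the antigen presentation genes, 3 of 11 rose and 0 fell (6 and 0 adjusted over the list alone). Of the homeostatic microglia markers, 5 of 9 rose and 0 fell (5 and 0 adjusted over the list alone). Of the extracellular matrix genes, 2 of 12 rose and 0 fell (6 and 0 adjusted over the list alone), namely S100a6 (1.22 ± 0.27) and Anxa2 (1.03 ± 0.19). Of the astrocyte identity genes, 3 of 13 rose and 0 fell (3 and 0 adjusted over the list alone), with Slc1a2, the main glutamate transporter of astrocytes, at 0.59 ± 0.12. The dentate granule cell list had 2 of 3 members higher (2 and 0 adjusted over the list alone). Its score was higher in 8 of 9 KA arrays than in every sham array (exact permutation test, adjusted p = 0.0133), while cameraPR gave adjusted p = 0.144. In the CA1 list 1 of 5 genes fell (0 and 1 adjusted over the list alone), Mpped1 (-0.58 ± 0.15). Among the sodium, calcium and HCN channels 1 of 13 fell (0 and 1 adjusted over the list alone), Scn3b (-0.71 ± 0.20), which was lost without IL KA replicate 1 or IL sham replicate 3 (adjusted p from 0.0623 to 0.0773). Median scaling ended both calls.

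At day 28 the injected side had 504 genes higher and 163 lower in KA (limma), 205 of them by more than 2-fold. Median scaling gave 486 and 30. Without KA replicate 1 the total of 667 became 440, and without sham replicate 5, which lay on slide 9, 416. Calls of Slc17a7, Vamp2 and Homer1 as higher rested on that sham array, at adjusted p = 0.92, 0.543 and 0.919 without it. Its pan-neuronal score was -1.09 against 0.03 to 0.21 in the other sham arrays. By cameraPR 11 lists were higher and 2 lower, and 6 and 0 with an estimated correlation. Activated microglia shifted by 1.76 (adjusted p = 1.05e-25; 1.92 with slide as a block and 1.85 to 2.93 within 2 slides). Neuropeptides and trophic factors shifted by 0.93 (adjusted p = 1.74e-11; 0.91 with slide as a block and 0.93 to 1.02 within slides), with 9 of 9 KA arrays above every sham array. All 13 lists kept direction with slide as a block and in both shared slides (2 KA, 2 sham arrays). Calls lost with an estimated correlation were interferon response (adjusted p = 1.97e-08 and, with an estimated correlation, 0.0687), lysosome (8.62e-06 and 0.0887), antigen presentation (2.29e-05 and 0.111), homeostatic microglia (3.75e-05 and 0.0967) and extracellular matrix (0.000349 and 0.0819). CA1 pyramidal cells shifted by -0.38 (adjusted p = 0.0399; adjusted p = 0.158 with an estimated correlation and 0.0892 with slide as a block) and were also lost without IL KA replicate 1, 7 or 8 or IL sham replicate 3 or 5 (adjusted p from 0.0506 to 0.125). Sodium, calcium and HCN channels shifted by -0.27 (adjusted p = 0.0384; adjusted p = 0.151 with an estimated correlation) and were lost without IL KA replicate 5 or 9 or IL sham replicate 1, 2 or 3 (adjusted p from 0.0536 to 0.132). Median scaling halved both shifts, to -0.19 and -0.13.

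At day 60, reactive astrocyte, complement and neuropeptide genes were higher in KA on the injected side, and a group of ion channel genes was lower. Of the reactive astrocyte genes, 12 of 17 rose and 0 fell (13 and 0 adjusted over the list alone), with Lcn2 at least 14-fold higher, Serpina3n, a protease inhibitor, at 2.32 ± 0.32 and Gfap at 2.12 ± 0.34. Of the complement genes, 4 of 6 rose and 0 fell (5 and 0 adjusted over the list alone), with C4b at 2.02 ± 0.30. Of the neuropeptides and trophic factors, 7 of 15 rose and 1 fell (8 and 1 adjusted over the list alone). Gal, the precursor of galanin, rose by 2.37 ± 0.44, Bdnf by 1.64 ± 0.30, Nptx2 by 1.57 ± 0.34 and Npy by 1.11 ± 0.24. The member that fell, Nts, the precursor of neurotensin (-0.76 ± 0.21), was named after its value was seen and was lost without sham replicate 3 or 5 (adjusted p = 0.102 and 0.218). Trh and Wfdc18 had the lowest adjusted p of the comparison (5.91 ± 0.56 and 3.19 ± 0.30, adjusted p = 1.22e-12 for each). Of the sodium, calcium and HCN channels, 0 of 13 rose and 3 fell (0 and 3 adjusted over the list alone). Scn3b fell by 1.10 ± 0.20 (adjusted p = 7.02e-05). In the CA1 pyramidal cell list, 0 of 5 rose and 1 fell (0 and 2 adjusted over the list alone). The member that fell was Pou3f1 (-1.01 ± 0.20, adjusted p = 0.000228). Cort fell by 1.03 ± 0.21.

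Of the activated microglia and macrophage markers at day 60, 6 of 13 rose and 1 fell (10 and 1 adjusted over the list alone), with Gpnmb at 3.45 ± 0.41 and Lyz2, lysozyme, at 1.82 ± 0.38. The member that fell, Itgb2, an integrin subunit of leukocytes (-0.50 ± 0.16, adjusted p = 0.0498), was named after its value was seen and was lost without any of 10 arrays, at adjusted p = 0.796 without sham replicate 5. Of the extracellular matrix genes, 3 of 12 rose and 0 fell (5 and 0 adjusted over the list alone), with Anxa2 at 1.28 ± 0.19. Of the cytokines and chemokines, 2 of 15 rose and 0 fell (4 and 0 adjusted over the list alone), with Ccl12 at 2.36 ± 0.42. Of the antigen presentation genes, 3 of 11 rose and 0 fell (5 and 0 adjusted over the list alone), and of the interferon response genes, 1 of 10 rose and 0 fell (4 and 0 adjusted over the list alone), namely Ifitm3 (1.38 ± 0.25). Of the lysosome genes, 1 of 12 rose and 0 fell (2 and 0 adjusted over the list alone). This was Ctsc, a cathepsin (0.74 ± 0.22), lost without IL KA replicate 1, 5, 6 or 7 or IL sham replicate 1, 2, 3 or 5 (adjusted p from 0.0503 to 0.131). Of the endothelial markers, 2 of 8 rose and 0 fell (2 and 0 adjusted over the list alone), and of the markers of mural cells and fibroblasts, 1 of 8 rose and 0 fell (2 and 0 adjusted over the list alone). The last was Lum, the proteoglycan lumican (0.85 ± 0.26), lost without IL KA replicate 1, 4, 5 or 7 or IL sham replicate 2 or 5 (adjusted p from 0.0536 to 0.222). Of the astrocyte identity genes, 1 of 13 rose and 0 fell (1 and 0 adjusted over the list alone), namely Slc1a2 at 0.73 ± 0.12, which median scaling ended. Aif1, the microglial marker Iba1, which rose by 2.02 ± 0.32 at day 7 and 1.21 ± 0.29 at day 28, had 0.57 ± 0.29 at day 60 (adjusted p = 0.319).

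In total 383 genes were higher and 149 lower in KA on the injected side at day 60 (limma), 160 of them by more than 2-fold. Median scaling gave 220 and 36. Without sham replicate 5, an array of slide 9 with 49.3% of probes detected, 293 genes passed. By cameraPR 12 lists were higher and 2 lower, and 4 and 1 with an estimated correlation. In all 4 shared slides (5 KA, 4 sham arrays), 13 of the 14 kept their direction. Reactive astrocytes shifted by 1.38 (adjusted p = 4.17e-22; 1.46 with slide as a block and 1.05 to 2.25 within 4 slides). Sodium, calcium and HCN channels shifted by -0.32 (adjusted p = 0.00415; -0.33 with slide as a block and -0.72 to -0.01 within slides). Neuropeptides and trophic factors shifted by 0.72 (adjusted p = 6.85e-06; 0.69 with slide as a block and 0.32 to 1.18 within slides). CA1 pyramidal cells shifted by -0.40 (adjusted p = 0.0248; adjusted p = 0.121 with an estimated correlation), -0.78 to 0.07 within slides, and were lost without IL KA replicate 5 or IL sham replicate 3 (adjusted p from 0.0532 to 0.0752). Activated microglia shifted by 1.05 (adjusted p = 1.57e-09; adjusted p = 0.068 with an estimated correlation). Other calls lost with an estimated correlation were antigen presentation (adjusted p = 0.000108 and, with an estimated correlation, 0.152), cytokines and chemokines (0.000228 and 0.249), lysosome (0.000502 and 0.204), interferon response (0.00272 and 0.416), endothelium (0.00579 and 0.204), mural cells and fibroblasts (0.00722 and 0.171) and astrocyte identity (0.0273 and 0.158). Astrocyte identity was also lost without IL sham replicate 2 or 3 (adjusted p from 0.0562 to 0.0644).

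Across the 3 days on the injected side, 131 genes were higher in KA at each day and 16 lower at each day. Days 7 and 28 shared 296 genes that rose, against 37.6 for independent lists of these sizes, and days 28 and 60 shared 186, against 17.0. Mat2b was the gene called in opposite directions, at -0.57 ± 0.15 at day 7 (adjusted p = 0.00712) and 0.57 ± 0.14 at day 60 (adjusted p = 0.00573); it was named after its values were seen. The difference between the KA effects of days 7 and 28 was itself tested, and 10 genes had a higher and 20 a lower effect at day 28 (limma). Wfdc18 had an effect larger by 2.67 ± 0.44 at day 28 (adjusted p = 0.000651). Ms4a7, a gene of macrophages, had an effect lower by 2.04 ± 0.43 (adjusted p = 0.0165), which was lost without IL sham replicate 4 (adjusted p = 0.0507). Median scaling gave 18 genes, and slide as a block 5. With each array left out the count of 30 ran from 9 to 178, the highest without IL KA replicate 8 of day 7. Between days 28 and 60, limma found 0 genes whose effect differed, with 940 at unadjusted p under 0.05.

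**Figure D3:**
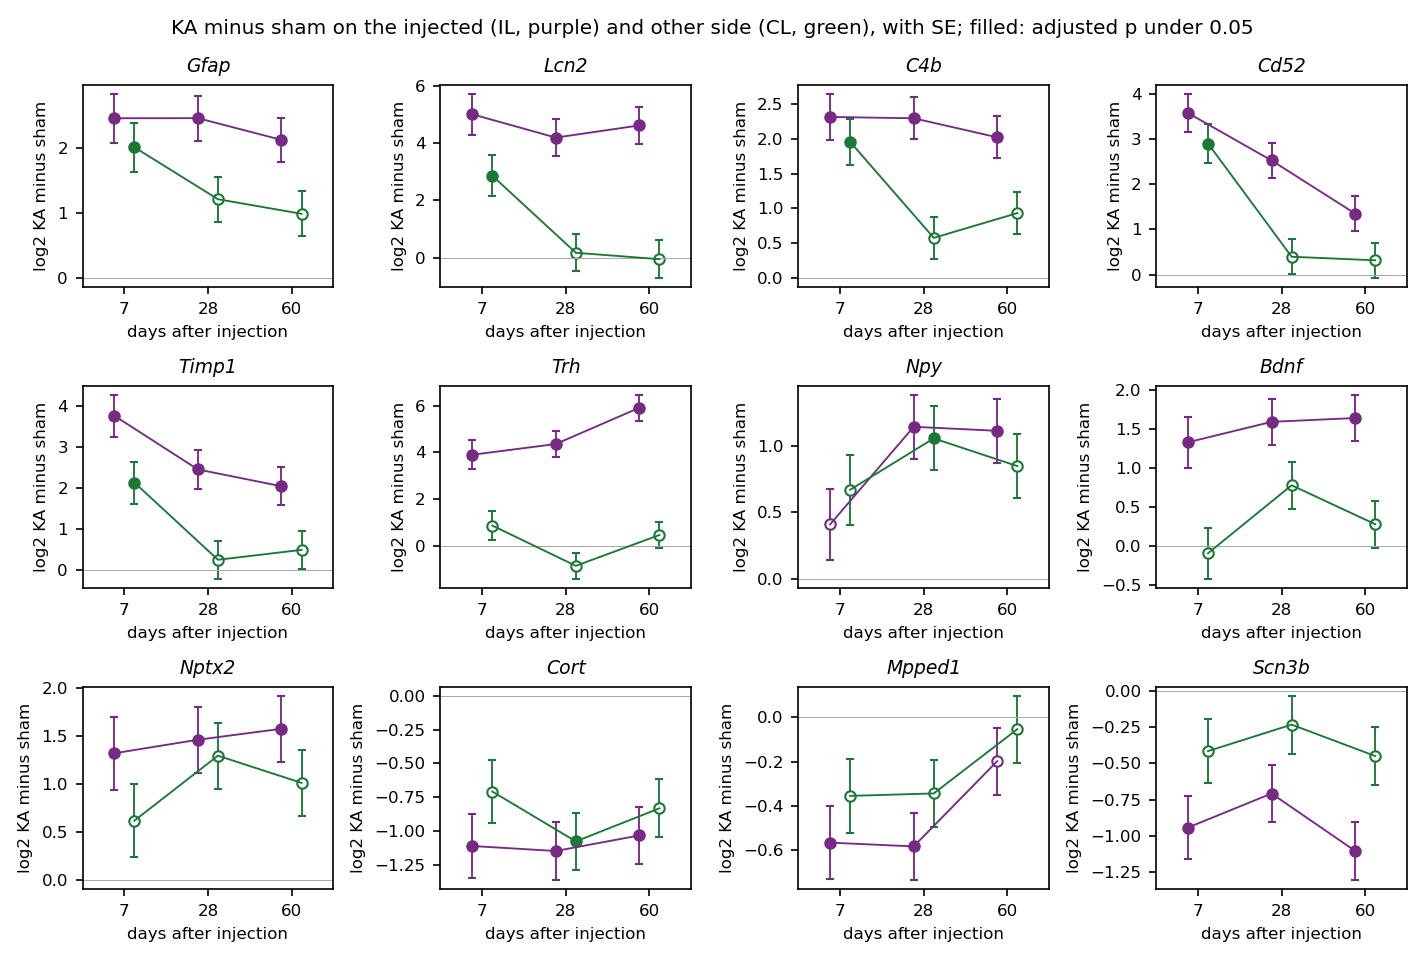
Log2 difference of KA and sham (points, with SE) of 12 genes by day, on the injected (purple) and the other side (green), filled where adjusted p was under 0.05; Lcn2 was not well above background in IL sham at any day, in CL sham at days 7 and 28 and in CL KA at day 60, and Timp1 in CL sham at day 60. Gfap, C4b and Trh are higher in KA than in sham on the injected side at each day, by 2.12 to 2.45, 2.02 to 2.31 and 3.90 to 5.91.

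The comparison on the side that received no injection asked whether the effect of kainate reached the other hippocampus. At day 7, glial and immune genes were higher in KA on that side too. Of the activated microglia and macrophage markers, 8 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), with Cd52 at 2.91 ± 0.43 (adjusted p = 2.17e-05, 8 of 8 KA arrays above every sham array) and Lyz2 at 2.02 ± 0.41. Of the interferon response genes, 8 of 10 rose and 0 fell (8 and 0 adjusted over the list alone), with Ifit3 at 1.93 ± 0.34. Ifi27l2a rose by 2.72 ± 0.49. Of the reactive astrocyte genes, 8 of 17 rose and 0 fell (10 and 0 adjusted over the list alone), with Gfap at 2.01 ± 0.38 (adjusted p = 0.000449) and Serpina3n at 1.80 ± 0.35. Of the cytokines and chemokines, 8 of 15 rose and 0 fell (10 and 0 adjusted over the list alone), with Ccl4 at 2.60 ± 0.46 and Cxcl10 at least 4.02-fold higher. Of the complement genes, 4 of 6 rose and 0 fell (5 and 0 adjusted over the list alone), with C4b at 1.95 ± 0.33 and C1qa at 1.75 ± 0.31. Of the lysosome genes, 4 of 12 rose and 0 fell (9 and 0 adjusted over the list alone), with Laptm5, a lysosomal membrane protein, at 1.25 ± 0.23. Of the antigen presentation genes, 2 of 11 rose and 0 fell (7 and 0 adjusted over the list alone). Of the homeostatic microglia markers, 3 of 9 rose and 0 fell (4 and 0 adjusted over the list alone). Of the extracellular matrix genes, 1 of 12 rose and 0 fell (3 and 0 adjusted over the list alone), namely S100a6 (1.06 ± 0.29), lost without CL KA replicate 2, 4, 5 or 8 or CL sham replicate 1, 2, 3 or 4 (adjusted p from 0.0678 to 0.138). Fos (1.18 ± 0.53, adjusted p = 0.473), Bdnf (-0.10 ± 0.33, adjusted p = 1) and Npy (0.67 ± 0.26, adjusted p = 0.324) did not pass.

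In total 170 genes were higher and 5 lower in KA on the other side at day 7 (limma), and 166 of the 170 were also higher on the injected side, against 12.7 for independent lists. The 5 genes that fell were Gdf10, Rapgef6, Nxph1, Twist1 and Msto1. Gdf10 was lost without CL KA replicate 5 or CL sham replicate 1, 2, 3 or 4 (adjusted p from 0.0708 to 0.0961), Rapgef6 without CL KA replicate 2 or 5 or CL sham replicate 1, 2 or 4 (adjusted p from 0.0513 to 0.16), Nxph1 without CL KA replicate 8 or CL sham replicate 3 or 4 (adjusted p from 0.0621 to 0.137), Twist1 without CL KA replicate 8 or CL sham replicate 2 or 3 (adjusted p from 0.0592 to 0.155) and Msto1 without CL KA replicate 2, 4, 6 or 8 or CL sham replicate 1, 2 or 3 (adjusted p from 0.0545 to 0.298). The count was 112, 101 and 89 without sham replicates 1, 3 and 4, and 114 without KA replicate 8. When the fit held only these 2 groups, 28 genes passed. By cameraPR 11 lists were higher and 2 lower, and 10 and 0 with an estimated correlation. In both shared slides (3 KA, 3 sham arrays), 11 of the 13 kept their direction. Activated microglia shifted by 1.46 (adjusted p = 8.51e-28; 1.38 with slide as a block and 0.73 to 1.97 within slides). Reactive astrocytes shifted by 1.10 (adjusted p = 1.5e-19; 1.07 with slide as a block and 0.64 to 1.33 within slides). Of the astrocyte identity genes, 0 of 13 rose and 0 fell (2 and 0 adjusted over the list alone), with a mean shift of 0.33 (adjusted p = 0.000282). Of the interneuron markers, 0 of 9 rose and 0 fell (0 and 2 adjusted over the list alone). Their mean shift was -0.26 (adjusted p = 0.0273; adjusted p = 0.095 with an estimated correlation), with 7 of 8 KA arrays below every sham array, and the call was lost without CL sham replicate 4 (adjusted p = 0.0706). Endothelial markers, of which 0 of 8 rose and 0 fell (1 and 0 adjusted over the list alone), shifted by 0.29 (adjusted p = 0.0107; adjusted p = 0.248 with an estimated correlation), a call lost with slide as a block (adjusted p = 0.112) and without CL KA replicate 5 or CL sham replicate 4 (adjusted p from 0.065 to 0.0989). Cholesterol synthesis genes, of which 0 of 12 rose and 0 fell (0 and 0 adjusted over the list alone), shifted by -0.25 (adjusted p = 0.00517; adjusted p = 0.345 with an estimated correlation). That list shifted by -0.14 with slide as a block, where it was lost (adjusted p = 0.112), and by -0.29 to 0.31 within slides, and was lost without CL KA replicate 5 (adjusted p = 0.0556).

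At day 28 on the other side, neuropeptide genes shifted upward together while few single genes passed. Of the neuropeptides and trophic factors, 1 of 15 rose and 0 fell (7 and 1 adjusted over the list alone), with Npy at 1.06 ± 0.24 (adjusted p = 0.0436). Their mean shift was 0.63 (adjusted p = 1.59e-08), 0.71 with slide as a block and 0.67 to 0.95 within 2 slides, with 8 of 9 KA arrays above every sham array. Nrn1 rose by 1.69 ± 0.37 (adjusted p = 0.035) and Tuba1a, a neuronal tubulin, by 0.97 ± 0.20. Cort fell by 1.08 ± 0.21 (adjusted p = 0.0185), as did 6 other genes: Etv4, Lypd2, Tirap, Ryr1, Matn4 and Bcl9l. Gfap did not pass at 1.21 ± 0.34 (adjusted p = 0.0816). In all 3 genes were higher and 7 lower (limma; 1340 at unadjusted p under 0.05). Median scaling gave 0 and 3, no background correction 14 and 17, and a fit of only these 2 groups 2 genes in all. With slide as a block Tuba1a, Etv4, Ryr1, Matn4 and Bcl9l were lost (adjusted p from 0.0531 to 0.0819), and without slides 4 and 9 Nrn1, Tuba1a and Matn4 (0.0535 to 0.105). Without sham replicate 3, an array of slide 4, 0 genes passed, and Cort, Etv4 and Lypd2, which kept their calls without any other single array, had adjusted p = 0.107, 0.107 and 0.109. Npy was lost without CL KA replicate 2, 3, 4, 5, 6 or 9 or CL sham replicate 3 (adjusted p from 0.0543 to 0.109), Nrn1 without CL KA replicate 2, 5, 6 or 9 or CL sham replicate 3 (adjusted p from 0.0508 to 0.256) and Tuba1a without CL KA replicate 9 or CL sham replicate 3 (adjusted p from 0.0742 to 0.29). Tirap was lost without CL KA replicate 2 or 9 or CL sham replicate 3 (adjusted p from 0.0507 to 0.164), Ryr1 without CL KA replicate 5, 6, 8 or 9 or CL sham replicate 3 or 5 (adjusted p from 0.0551 to 0.107), Matn4 without CL KA replicate 2, 5, 6, 8 or 9 or CL sham replicate 3 (adjusted p from 0.0567 to 0.132) and Bcl9l without CL KA replicate 1 or 9 or CL sham replicate 3 or 5 (adjusted p from 0.0714 to 0.128). With each array left out the count ran from 0 to 219.

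Another 5 lists were higher and 1 lower by cameraPR on the other side at day 28, and 0 of these 6 with an estimated correlation. Counting the neuropeptides, 5 of the 7 called lists kept their direction in both shared slides (3 KA, 2 sham arrays). Of the oxidative phosphorylation genes, 0 of 11 rose and 0 fell (3 and 0 adjusted over the list alone), with a mean shift of 0.43 (adjusted p = 0.00219; adjusted p = 0.135 with an estimated correlation). That call was lost without CL sham replicate 3 (adjusted p = 0.516), an array whose score of the list was -2.15 against -0.18 to 0.13 in the other sham arrays. Without slides 4 and 9 it was lost too (adjusted p = 0.359), as were the pan-neuronal (0.418), reactive astrocyte (0.0574) and erythrocyte (0.217) calls. Of the CA2 and CA3 pyramidal cell markers, 0 of 6 rose and 0 fell (3 and 0 adjusted over the list alone), with a mean of 0.41 (adjusted p = 0.0022; adjusted p = 0.135 with an estimated correlation), lost without CL sham replicate 4 (adjusted p = 0.0951). Of the pan-neuronal markers, 0 of 10 rose and 0 fell (2 and 0 adjusted over the list alone), with a mean of 0.29 (adjusted p = 0.0412; adjusted p = 0.151 with an estimated correlation and 0.272 with slide as a block), also lost without CL KA replicate 1, 6, 7, 8 or 9 or CL sham replicate 3 (adjusted p from 0.0532 to 0.614). Among the activated microglia markers, 0 of 13 rose and 0 fell (1 and 0 adjusted over the list alone), with a mean of 0.40 (adjusted p = 0.00609; adjusted p = 0.503 with an estimated correlation). Their list score lay above every sham array in 9 of 9 KA arrays (exact permutation test, adjusted p = 0.0133), and the cameraPR call was kept whichever single array was left out. Of the reactive astrocyte genes, 0 of 17 rose and 0 fell (2 and 0 adjusted over the list alone), with a mean of 0.27 (adjusted p = 0.0239; adjusted p = 0.588 with an estimated correlation and 0.0714 with slide as a block), also lost without CL KA replicate 6 or CL sham replicate 2 or 3 (adjusted p from 0.0513 to 0.0704); the list score gave adjusted p = 0.021, with 8 of 9 KA arrays above every sham array (exact permutation test). Of the erythrocyte markers, 0 of 3 rose and 0 fell (0 and 2 adjusted over the list alone), with a mean of -0.74 (adjusted p = 0.033; adjusted p = 0.204 with an estimated correlation), lost without CL KA replicate 4 or 8 or CL sham replicate 4 (adjusted p from 0.0682 to 0.199). Leaving out slides 4 and 9 was chosen after seeing the data.

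At day 60 on the other side, 6 genes were higher and 1 lower in KA (limma; 849 at unadjusted p under 0.05). Rprm rose by 1.46 ± 0.25 (adjusted p = 0.00109) and kept its call whichever single array was left out, but had adjusted p = 0.407 without slides 4 and 9, where Drd1, Col6a1, Igsf9 and Lrpap1 were lost as well. Drd1, the D1 dopamine receptor, rose by 1.23 ± 0.24 and Col6a1, a collagen chain, by 1.32 ± 0.26; both were lost without sham replicate 4, an array of slide 9 (adjusted p = 0.176 and 0.192). Tmc6 rose by 1.08 ± 0.21 and was lost without CL sham replicate 3 (adjusted p = 0.0953). Igsf9 (0.93 ± 0.19) and Lrpap1 (0.64 ± 0.14) rose as well, and Rtl3, not well above background in KA, fell (adjusted p = 0.0136). Igsf9 was lost without CL KA replicate 1 or 8 or CL sham replicate 3, 4 or 5 (adjusted p from 0.0513 to 0.158), Lrpap1 without CL KA replicate 1, 3 or 8 or CL sham replicate 4 (adjusted p from 0.0546 to 1) and Rtl3 without CL sham replicate 1, 3 or 5 (adjusted p from 0.0779 to 0.145). Gfap (0.99 ± 0.34, adjusted p = 0.403) and Npy (0.85 ± 0.24, adjusted p = 0.251) did not pass. The count of 7 was 11 without sham replicate 2 and 3 without sham replicate 4. Median scaling gave 1 gene higher and 0 lower, no background correction 8 and 4, the values of the series matrix 6 and 0, and a fit of only these 2 groups 0 genes. With slide as a block Col6a1, Tmc6 and Lrpap1 were lost (adjusted p from 0.0517 to 0.0648).

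By cameraPR 2 lists were higher and 1 lower on the other side at day 60, and 0 with an estimated correlation. In both shared slides (2 KA, 2 sham arrays), 2 of the 3 kept their direction. Of the immediate early genes, 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone), with a mean shift of -0.45 (adjusted p = 0.000257; adjusted p = 0.168 with an estimated correlation), -0.64 with slide as a block and -1.06 to -0.69 within 2 slides. Their list score did not pass (exact permutation test, adjusted p = 0.237), with 6 of 9 KA arrays below every sham array. Of the neuropeptides and trophic factors, 0 of 15 rose and 0 fell (3 and 0 adjusted over the list alone), with a mean of 0.28 (adjusted p = 0.0239; adjusted p = 0.249 with an estimated correlation, 0.0741 with slide as a block and 0.282 by list score), also lost without CL KA replicate 1 or 8 or CL sham replicate 1 (adjusted p from 0.0541 to 0.203). Of the activated microglia markers, 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone), with a mean of 0.33 (adjusted p = 0.034; adjusted p = 0.635 with an estimated correlation), lost without CL KA replicate 1, 2, 3 or 4 or CL sham replicate 2, 3 or 5 (adjusted p from 0.0555 to 0.0953). The list score was higher in microglia (adjusted p = 0.021) and complement (adjusted p = 0.0412), with 7 of 9 KA arrays above every sham array in each (exact permutation test), while cameraPR did not call complement (adjusted p = 0.113). For the difference between days in the KA effect on the other side, limma found 0 genes between days 7 and 28 (1114 at unadjusted p under 0.05) and 0 between days 28 and 60 (1129). The first count was 230 with array weights and 39 without CL KA replicate 7 of day 7.

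**Figure D4:**
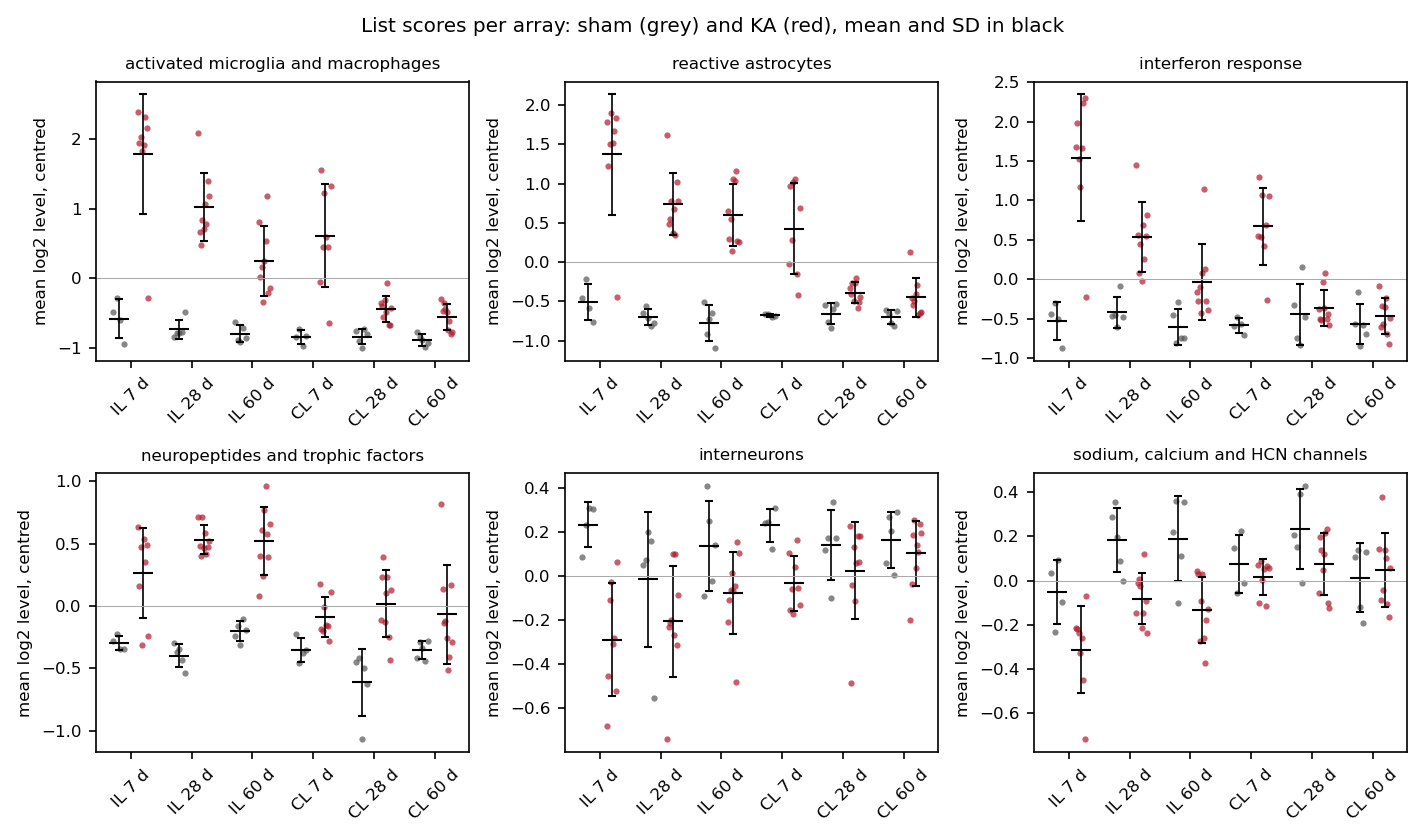
List scores per array (points; mean log2 deviation of a list's members) with group means, by day, hemisphere and treatment. In the activated microglia and macrophage list, 7 KA arrays of the injected side at day 7 lie between 1.84 and 2.38 and KA replicate 8 lies at -0.28.

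The difference between the KA effects of the injected and the other side was tested directly, gene by gene. At day 7, 3 genes had a larger effect on the injected side and 0 a smaller one (limma, 511 at unadjusted p under 0.05). These were Acan, the cartilage proteoglycan aggrecan of perineuronal nets (adjusted p = 0.00592), and Phf11a (adjusted p = 0.0137), both not well above background in IL sham, and Cdc20 (1.15 ± 0.23, adjusted p = 0.0204). Phf11a was lost without CL sham replicate 4 or IL sham replicate 4 (adjusted p from 0.0617 to 0.0656) and Cdc20 without CL KA replicate 6, 7 or 8 or CL sham replicate 1 or 4 or IL KA replicate 1 or 7 or IL sham replicate 2, 3 or 4 (adjusted p from 0.05 to 0.146). The count was 95 without IL KA replicate 8, 8 without CL KA replicate 2 or IL KA replicate 4, and 1 without IL or CL sham replicate 4. At day 28, 101 genes had a larger and 15 a smaller effect on the injected side (median scaling 168 and 4). Trh differed by 5.21 ± 0.76 (adjusted p = 1.01e-05) and Cartpt by 5.59 ± 0.89. The count of 116 was 70 without IL KA replicate 1 and 202 without IL sham replicate 2. At day 60, 59 genes had a larger and 15 a smaller effect on the injected side. Wfdc18 differed by 3.10 ± 0.40 (adjusted p = 2.5e-07), Nmbr by 2.99 ± 0.39 and Trh by 5.44 ± 0.76. With each array left out the count of 74 ran from 36 to 85. Gfap differed by 0.45 ± 0.51, 1.25 ± 0.47 and 1.14 ± 0.47 at the 3 days and did not pass (adjusted p = 1, 0.161 and 0.315).

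Among the lists, cell cycle genes differed most clearly between the sides at day 7, with 1 of 11 larger on the injected side (4 and 0 adjusted over the list alone) and a mean difference of 0.66 (adjusted p = 2.42e-13; adjusted p = 7.43e-06 with an estimated correlation). Lysosome genes differed by 0.65 (adjusted p = 4.8e-10; adjusted p = 0.0315 with an estimated correlation). With the preset correlation, cameraPR called 12 lists larger and 1 smaller on the injected side at day 7, 10 and 2 at day 28 and 11 and 1 at day 60, and with an estimated correlation 2, 1 and 0. At day 7 activated microglia differed by 0.91 (adjusted p = 7.94e-10; adjusted p = 0.0746 with an estimated correlation), reactive astrocytes by 0.77 (adjusted p = 7.94e-10; adjusted p = 0.0636 with an estimated correlation) and synapse genes by -0.21 (adjusted p = 0.0364; adjusted p = 0.176 with an estimated correlation). The synapse call was lost without CL sham replicate 2, 3 or 4 or IL KA replicate 4 or 7 or IL sham replicate 1 or 3 (adjusted p from 0.0555 to 0.117). At day 28 complement genes, of which 5 of 6 were larger (5 and 0 adjusted over the list alone), differed by 1.37 (adjusted p = 6.33e-09; adjusted p = 0.0315 with an estimated correlation). Activated microglia, with 5 of 13 larger (10 and 0 adjusted over the list alone), differed by 1.36 (adjusted p = 3.63e-11; adjusted p = 0.0636 with an estimated correlation). The CA2 and CA3 pyramidal cell markers, with 0 of 6 smaller (0 and 3 adjusted over the list alone), differed by -0.73 (adjusted p = 0.000518; adjusted p = 0.0968 with an estimated correlation). Choroid plexus markers differed by -1.38 (adjusted p = 0.031; adjusted p = 0.47 with an estimated correlation), and that call was lost without CL KA replicate 1 or 8 or CL sham replicate 2, 3 or 4 or IL KA replicate 2 or 7 or IL sham replicate 4 or 5 (adjusted p from 0.0527 to 0.148) and with slide as a block (adjusted p = 0.607). Without slides 4 and 9 its sign turned (adjusted p = 0.976). At day 60 reactive astrocyte genes, with 3 of 17 larger (10 and 0 adjusted over the list alone), differed by 1.13 (adjusted p = 3.91e-12; adjusted p = 0.0537 with an estimated correlation), and sodium, calcium and HCN channels by -0.36 (adjusted p = 0.00922; adjusted p = 0.0807 with an estimated correlation).

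The direct comparison of both hippocampi of the same KA animals gave 384 genes higher and 118 lower on the injected side at day 7, 416 and 61 at day 28, and 298 and 156 at day 60 (limma; median scaling at day 60 gave 212 and 45). Cartpt was higher on the injected side by 4.03 ± 0.56, 5.19 ± 0.53 and 4.55 ± 0.53 at the 3 days, and Trh by 3.13 ± 0.48, 4.50 ± 0.45 and 5.36 ± 0.45. The count of 502 at day 7 ran from 302 to 867 with each array left out. The count of 477 at day 28 was 306 without IL KA replicate 1. In sham animals, where both sides differed by the saline injection, limma found 0 genes at day 7 (127 at unadjusted p under 0.05), 1 at day 28 (1236) and 0 at day 60 (672). The gene at day 28 was Kank2, an adaptor of cell adhesions (adjusted p = 0.0318), not well above background on the injected side and at least 1.15-fold lower there. It was lost with slide as a block, where 0 genes passed. With each array left out the count at day 28 ran from 0 to 147.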

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

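In this part the tests of explanations were chosen after the results were seen, and so were the counts of other splits of the samples; the tests of differences between sides and days were planned. The difference between the KA effects of the IL and CL side passed for 3, 116 and 74 genes at days 7, 28 and 60 and for 13, 12 and 12 gene lists, of which 3 of 37 passed with an estimated correlation and 10 with fry. The change of the KA effect from day 7 to day 28 on the IL side passed for 30 genes. Of 420 combinations of a gene list and a group of arrays, 44 had 1 array far from the others, where 21 would be expected, since chance flags about 1 in 20 groups. These lay on 20 arrays, 7 of them with more than 2, and 19 of the 44 on the 11 arrays of slides 4 and 9. In the percent of probes detected, 3 arrays of slide 9 stood apart: CL sham day 60 replicate 4 (46.8%), IL KA day 60 replicate 7 (49.9%) and IL sham day 60 replicate 5 (49.3%).

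IL KA day 7 replicate 8 stood apart in 8 lists: activated microglia (-0.28 against 1.84 to 2.38), reactive astrocytes (-0.45 against 1.23 to 1.90), complement (-0.33), interferon response (-0.23), extracellular matrix (-0.31), lysosome (-0.00) and astrocyte identity (0.02) were low, and pan-neuronal markers (0.26 against -0.41 to -0.13) high. On the CL side, KA day 7 replicate 7, of the same animal, had a thalamus score of 1.87 against -0.37 to 0.05. IL sham day 28 replicate 5 was low in oligodendrocyte precursors (-1.11), pan-neuronal markers (-1.09), synapse (-0.94), oxidative phosphorylation (-0.76) and interneurons (-0.55), and high in activated microglia (-0.48 against -0.84 to -0.77). CL sham day 28 replicate 3 was low in oxidative phosphorylation (-2.15), pan-neuronal markers (-1.19) and astrocyte identity (-0.75). CL KA day 28 replicate 4 was low in oxidative phosphorylation (-0.90), synapse (-0.63) and pan-neuronal markers (-0.37). CL KA day 60 replicate 3 was low in myelinating oligodendrocytes (-1.56) and oxidative phosphorylation (-1.18) and high in synapse (0.42).

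IL KA day 28 replicate 1 was high in cytokines and chemokines (1.61) and homeostatic microglia (1.10) and low in interneurons (-0.74). IL KA day 60 replicate 7 was low in newborn neurons (-0.74) and pan-neuronal markers (-0.42) and high in oligodendrocyte precursors (0.22). CL KA day 28 replicate 2 was high in cell cycle (0.16) and low in interneurons (-0.48), and CL sham day 7 replicate 4 was high in oxidative phosphorylation (0.27) and pan-neuronal markers (0.28). Single lists stood apart in the following arrays. At day 7 these were CL KA replicate 5 and IL KA replicate 4, both of 1 animal, in endothelium (0.98 and 1.03), and CL sham replicate 1 in thalamus (-0.20). That animal also had the lowest KA scores of cholesterol synthesis (-0.69 and -0.67) and erythrocytes (-1.39 and -1.48) on both sides, and the CL day 7 calls of endothelium and cholesterol synthesis were lost without its CL array. At day 28 CL sham replicate 4 was high in erythrocytes (1.23). At day 60 IL sham replicate 2 was high in choroid plexus (0.21), IL KA replicate 6 in interferon response (1.14) and CL KA replicate 1 in reactive astrocytes (0.13). IL KA replicate 1 was low in dentate granule cells (-1.09), IL sham replicate 3 in potassium channels (-0.15) and CL sham replicate 4 in oligodendrocyte precursors (-0.39).

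The first pattern weighed is the KA animal of day 7 whose IL array lay near the sham arrays, in activated microglia just above the highest of them (-0.28 against -0.29). A swap with a sham animal of day 7 would need a sham array in place of a KA array, and 0 sham IL arrays scored above 1.84 in activated microglia; a dim array is argued against by its 62.4% of probes detected, within the 62.3% to 66.9% of the other KA IL arrays. An animal without any kainate effect stays open. Its CL joint score of microglia and reactive astrocytes was -0.52 against -0.81 to -0.69 in sham (SD 0.05), with the other KA arrays at -0.04 or above. But the same array stood apart in thalamus (1.87), so other tissue may have moved this score. A wrong label of the IL array without a partner, or kainate that missed the tissue taken, stays open: the projection on the KA effect of the other animals was 0.12 on the IL side (sham -0.10 to 0.08, other KA 0.81 to 1.12). No biological explanation was tested.

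The second pattern is the rise of glial and immune lists on the CL side at day 7 with fewer called genes at days 28 and 60. Noise widens a spread and leaves the size of an effect, so noisier arrays as the whole cause are argued against by the CL effect in the joint score of microglia and reactive astrocytes, 1.26 at day 7 and 0.33 at day 28, a change of -0.93 ± 0.23 (SE from each group's own spread). The median SD within CL groups was 0.279 and 0.305 at days 28 and 60 against 0.243 at day 7, but 0.224 and 0.208 without slides 4 and 9, where 86 and 2 genes still passed against 281. For the gene count of day 60 this argues against noise as the whole cause, since with each array left out it was 3 to 11 against 89 to 222 at day 7. At day 28 the range was 0 to 219, and noise stays open for its count. Slides are argued against by the same change with slide in the fit, -0.87 ± 0.36 (SE; -0.93 ± 0.33 without). RNA carried over from the injected side would bring 1 common share of every IL rise and stays open. Of 388 genes raised over 2-fold on the IL side, 337 were above background, on at least 1 array, in all 4 groups of day 7. Their median share was 40.8% and single shares ran from -4.3% to 118.1%, but 12 lay over 2 SE from the common share (10 below, 2 above), where chance gives 16.9, and 0 at adjusted p under 0.05. Cartpt (-0.2%) and Trh (6.0%), outside the lists, were among those below. Members of glial and immune lists had 43.7% (62 genes) and those of the neuropeptide and immediate early lists, Igf1 among them, 32.4% (9 genes), a difference of 11.3 (permutation p = 0.085). The test of the change between days 7 and 28 passed for 0 CL genes (limma), but for 230 with array weights, 120 without both arrays of 1 KA animal of day 7, 44 without slides 4 and 9 and 39 without CL KA replicate 7 of day 7, so gene by gene a change is neither shown nor excluded. A glial response of the CL hippocampus that wanes may also be at work, which remains a hypothesis and untested.

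The third pattern is the lower interneuron list on the injected side at day 7. A dilution of all neuronal RNA by glial RNA would lower both neuronal lists alike, but the interneuron minus pan-neuronal score differed by -0.25 between KA and sham (exact permutation p = 0.0364, 6 of 8 KA arrays below every sham array), while the pan-neuronal score itself differed by -0.27 (exact permutation p = 0.0303). Slides are argued against by a KA effect of -0.57 ± 0.11 (SE) with slide in the fit. A loss of interneurons and a lower level of these transcripts in living cells were not tested and both stay open.

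Other splits of the same arrays into groups of the same sizes were fitted, 100 per comparison with the real one included. A share of splits as large under 0.05 was taken to argue against chance, without correction for the number of comparisons. The gene counts of KA against sham on the IL side lay above every other split drawn. They were 1195, 667 and 532 genes against at most 787, 283 and 220, with 1 of 100 splits as large each time. It can be excluded for CL day 7 (175, highest other 215, 2 of 100 as large) but not for CL day 28 (10, highest other 77, 11 as large) or CL day 60 (7, highest other 91, 24 as large). Splits that called 77 and 91 genes, several times the real counts, point to a structure of the samples. Of 3 arrays on the dim slides at each of these days, 2 were KA arrays; the 5 highest splits put 1 of them in the KA group at day 28 and 0 to 1 at day 60. Chance can be excluded for the hemisphere differences (3, 116 and 74 genes; highest others 2, 7 and 24; 1 of 100 each; at day 7 barely, since 1 gene passed without IL or CL sham replicate 4), for IL against CL in KA (502, 477 and 454; highest others 599, 360 and 236; 2, 1 and 1 as large) and for the IL change from day 7 to 28 (30, highest other 1, 1 as large). For the IL change from day 28 to 60 (0, highest other 4) and the CL changes (0 and 0, highest others 34 and 24), 100 of 100 splits are as large by construction, since 0 genes passed, and the splits say nothing. In sham, the splits are too few for a share under 0.05: 8 of 8, 7 of 16 and 16 of 16 were as large, with 0, 1 and 0 genes and highest others 0, 11 and 0.

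The number of lists called by cameraPR was here adjusted over the 35 lists of 1 comparison. Its share of splits as large was under 0.05 only for IL day 60 (16 lists, highest other 14, 1 of 100 as large) and for the hemisphere difference at day 60 (12, highest other 12, 2 as large). For IL days 7 and 28 the number of lists was 16 and 13, with 19 and 17 as the highest others and 13 and 11 splits as large. For CL days 7, 28 and 60 it was 13, 5 and 1, with highest others of 17, 7 and 5 and 25, 5 and 38 as large. For the hemisphere difference at days 7 and 28 it was 13 and 12, with highest others of 17 and 13 and 14 and 7 as large. Where other splits called as many lists, the number of lists does not set the real groups apart from chance, and the tests of single lists with an estimated correlation and by list score carry more weight.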

How the results depend on the processing

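The alternatives that leave out slides 4 and 9, or both arrays of 1 KA animal of day 7, were chosen after seeing the data; the others were planned. Named genes of the glial, complement and neuropeptide groups on the injected side kept their direction in the alternatives run. With slide as a block, 73 of 73 named calls at IL day 7, 65 of 65 at day 28 and 56 of 56 at day 60 had the same direction, and 71, 56 and 55 also passed. On the CL side at day 7, 39 of 39 had the same direction and 31 passed, at days 28 and 60 10 of 10 and 7 of 7, and 5 and 4 passed. In the hemisphere differences 3 of 3, 5 of 10 and 10 of 10 named calls passed, and in the IL change from day 7 to 28, 3 of 10. In no list called by cameraPR did another scaling change the sign of the mean shift (64 lists in KA against sham, 37 in the hemisphere differences), while 21 and 20 lists that were not called changed sign. Gene counts in the reported analysis were 1195, 667 and 532 for the IL side at days 7, 28 and 60, 175, 10 and 7 for the CL side, 3, 116 and 74 for the hemisphere difference, 502, 477 and 454 for IL against CL in KA, 0, 1 and 0 in sham, 30 and 0 for the IL changes and 0 and 0 for the CL changes. Counts below are those that moved by more than 1.5 times; the cause was not tested unless stated.

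Median scaling gave 779 in IL day 7, 256 in IL day 60, 3 in CL day 28, 1 in CL day 60, 9 in hemisphere difference day 7, 38 in hemisphere difference day 60, 257 in IL against CL in KA day 60, 0 in IL against CL in sham day 28, 18 in IL change from day 7 to 28 and 7 in CL change from day 7 to 28. No background correction gave 31 in CL day 28, 12 in CL day 60, 11 in hemisphere difference day 7, 3 in IL against CL in sham day 28, 1 in IL against CL in sham day 60, 2 in IL change from day 28 to 60, 2 in CL change from day 7 to 28 and 1 in CL change from day 28 to 60. Without a filter the count was 4 in IL against CL in sham day 28. The strict filter, which tests fewer genes, gave 24 in CL day 28, 0 in hemisphere difference day 7, 0 in IL against CL in sham day 28 and 13 in IL change from day 7 to 28. The mean of the kept probes gave 30 in CL day 28 and 54 in IL change from day 7 to 28. The series matrix values and the trend with robust variance moved 0 counts by this much.

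The treatment of blocks mattered for small counts. Without an animal block the counts were 46 in hemisphere difference day 60 and 0 in IL against CL in sham day 28. With animal as a fixed block the hemisphere difference at day 7 had 6 genes. With the replicate number as a block, which does not pair the arrays of an animal, they were 12 in CL day 60, 0 in IL against CL in sham day 28 and 2 in CL change from day 7 to 28. With slide as a block they were 805 in IL day 60, 11 in hemisphere difference day 7, 114 in hemisphere difference day 60, 296 in IL against CL in KA day 7, 0 in IL against CL in sham day 28 and 5 in IL change from day 7 to 28. Array weights gave 3149 in IL day 7, 1081 in IL day 28, 931 in IL day 60, 652 in CL day 7, 288 in CL day 28, 4 in CL day 60, 317 in hemisphere difference day 7, 414 in hemisphere difference day 28, 166 in hemisphere difference day 60, 1715 in IL against CL in KA day 7, 970 in IL against CL in KA day 28, 5 in IL against CL in sham day 7, 3 in IL against CL in sham day 28, 1 in IL against CL in sham day 60, 490 in IL change from day 7 to 28, 2 in IL change from day 28 to 60, 230 in CL change from day 7 to 28 and 1 in CL change from day 28 to 60. A fit of only the groups compared, which has fewer arrays to estimate the variance, gave 422 in IL day 28, 339 in IL day 60, 28 in CL day 7, 2 in CL day 28 and 0 in CL day 60.

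Leaving out slide 1 gave 738 in IL day 7, 59 in hemisphere difference day 28, 287 in IL against CL in KA day 28, 49 in IL against CL in sham day 28, 1 in IL change from day 28 to 60 and 1 in CL change from day 28 to 60. Leaving out slides 4 and 9 gave 2217 in IL day 7, 372 in IL day 28, 281 in CL day 7, 86 in CL day 28, 2 in CL day 60, 7 in hemisphere difference day 7, 31 in hemisphere difference day 28, 40 in hemisphere difference day 60, 1429 in IL against CL in KA day 7, 1 in IL against CL in sham day 7, 0 in IL against CL in sham day 28, 4 in IL change from day 7 to 28 and 44 in CL change from day 7 to 28. Without them Vamp2, higher at IL day 28 in the reported analysis, had -0.06 (adjusted p = 0.84), and the choroid plexus list in the hemisphere difference at day 28 changed its sign (adjusted p = 0.976). Leaving out both arrays of 1 KA animal of day 7 gave 265 in CL day 7, 63 in hemisphere difference day 7, 219 in hemisphere difference day 28, 203 in IL change from day 7 to 28, 4 in IL change from day 28 to 60 and 120 in CL change from day 7 to 28. With an estimated correlation 34 of the 64 list calls in KA against sham and 3 of the 37 in the hemisphere differences passed. With slide as a block 56 and 32 passed. Fry called 54 of the 64 and 10 of the 37. In KA against sham it also called 7 lists lower at IL day 7, where cameraPR called 1, and 0 lists at CL day 60, where cameraPR called 3. Of the 64 the list score test called 53. The 11 it did not call, at adjusted p from 0.0503 to 0.41, were 1 at each IL day, cholesterol synthesis, endothelium and homeostatic microglia at CL day 7, CA2 and CA3 cells, oxidative phosphorylation and pan-neuronal markers at CL day 28, and immediate early genes and neuropeptides at CL day 60. In all it called 57 lists; within slides, 47 of these moved by less than the spread between animals and 10 by more.

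With each array left out in turn, the counts at days 7, 28 and 60 ranged over 835 to 1493, 416 to 870 and 293 to 653 on the IL side, 89 to 222, 0 to 219 and 3 to 11 on the CL side and 1 to 95, 70 to 202 and 36 to 85 for the hemisphere difference. IL against CL ranged over 302 to 867, 306 to 522 and 307 to 492 in KA and 0 to 0, 0 to 147 and 0 to 0 in sham. The changes of the KA effect ranged over 9 to 178 and 0 to 3 on the IL side and 0 to 39 and 0 to 1 on the CL side. Among named calls, 57 of 73, 43 of 65 and 33 of 56 on the IL side and 24 of 39, 0 of 10 and 1 of 7 on the CL side kept their call whichever array was left out. Signal over background limits what can be seen of dim genes: 4598 probes were under the filter and 118 of 452 fixed list members had no kept probe. On the dimmest slides 51.4% and 56.8% of probes were detected, so falls of weakly expressed genes there rest on few detected values.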

Other observations

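The test of hypothesis in this part was chosen after the list scores were seen; the list tests were planned. Several lists were called by cameraPR in no KA against sham comparison. On the IL side at days 7, 28 and 60, T cell markers shifted by 0.18 (adjusted p = 0.515), 0.15 (adjusted p = 0.45) and 0.15 (adjusted p = 0.537). Markers of myelinating oligodendrocytes shifted by 0.19 (adjusted p = 0.739), 0.27 (adjusted p = 0.27) and -0.04 (adjusted p = 0.739), and markers of their precursors by 0.20 (adjusted p = 0.576), 0.28 (adjusted p = 0.251) and -0.00 (adjusted p = 0.995). Newborn neuron markers, among them Dcx, the microtubule protein of migrating neurons, shifted by -0.09 (adjusted p = 0.732), -0.05 (adjusted p = 0.805) and 0.06 (adjusted p = 0.911). Thalamus markers, a list for tissue from outside the hippocampus, shifted by 0.09 (adjusted p = 0.979), -0.18 (adjusted p = 0.597) and -0.01 (adjusted p = 0.976). Of the 5 T cell, 10 oligodendrocyte, 5 precursor, 6 newborn neuron and 6 thalamus genes tested, 0 passed on either side at any day (limma; 1 and 0 adjusted over the list alone in oligodendrocytes at IL day 28).

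Potassium channel genes shifted by -0.22 (adjusted p = 0.154), -0.07 (adjusted p = 0.748) and -0.07 (adjusted p = 0.805) on the IL side. Circadian clock genes shifted by -0.23 (adjusted p = 0.434), 0.00 (adjusted p = 0.939) and -0.11 (adjusted p = 0.656). Choroid plexus markers shifted by -0.70 (adjusted p = 0.472), -0.91 (adjusted p = 0.143) and 0.06 (adjusted p = 0.991).

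A hypothesis was that the strength of the astrocyte response varies between animals and affects both hippocampi of an animal. It was tested as the correlation of the reactive astrocyte score between the IL and CL array over the KA animals of each day, 3 tests in the family. At day 7, Spearman's rho was 0.76 (exact permutation p = 0.0368, adjusted 0.11, 8 animals) and Pearson's r 0.66 (exact permutation p = 0.0215, adjusted 0.0644), 0.82 without the 2 animals farthest from the median and 0.68 after adjusting for slide. At day 28, rho was -0.57 (permutation p = 0.121, adjusted 0.181, 9 animals) and r -0.52 (permutation p = 0.145, adjusted 0.218), -0.46 without 2 animals and -0.22 adjusted for slide. At day 60, rho was 0.13 (permutation p = 0.744, adjusted 0.744, 9 animals) and r 0.42 (permutation p = 0.282, adjusted 0.282), 0.80 without 2 animals and 0.17 adjusted for slide. No day passed the correction, the sign differed between days, and the question stays open with 8 or 9 animals.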
